A study of Mus musculus with 4 samples.

How the data were processed

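RNA was measured in CD8 T cells sorted by flow cytometry from the livers of C57BL/6 mice after 4 weeks on an MCD diet, per the labels' protocols. There were 2 samples labelled wild type and 2 labelled perforin knockout, and groups and replicate numbers were taken from the sample titles. Total RNA was made into libraries with a TruSeq RNA kit, which does not mark the strand of origin, and sequenced on an Illumina HiSeq, per the labels' protocols. The labels do not say whether the 2 samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

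Bowtie 0.12.2 and the mouse genome build mm8 are named, per the submitters' processing notes, with no role given. The quantification tool, the annotation and any filter are not given in the sources used here. The deposited table held 1 value per gene symbol and sample for 15367 symbols, of which 1468 were at 0 in every sample. Neither its header nor the labels named the unit. The deposited values were read as FPKM (fragment counts scaled to transcript length and library total), since they were not whole numbers, did not sum to a common total and had lower smallest values for longer transcripts. The columns summed to 378364 and 392785 in the wild type libraries and to 334493 and 383498 in the libraries labelled perforin knockout. Values of this kind do not carry the number of reads, so the depth of each library is unknown and no counting interval or detection floor was computed. No coordinates are given, because the only annotation used here (GENCODE M21) belongs to a later build than mm8. That annotation served for transcript lengths and for the names of overlapping genes.

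The values were analysed as log2(FPKM + 1), without further scaling, in R 4.3.3 with limma 3.58.1. Genes with a mean of at least 1 over the 4 libraries were tested, which left 9805. Fold changes are on this scale, labelled knockout minus wild type, and understate the change of weakly expressed genes. The 2 groups were compared with limma's moderated test with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. An exact permutation test of 2 samples against 2 cannot give a two-sided p below 0.333.

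The groups, the tests, the other settings to be tried, the rule for named genes and 32 gene lists were fixed before the data were examined. The lists cover T cell functions, stress, metabolism, the neighbourhood of Prf1 and markers of other cells a liver sort could hold. They were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the 32 lists. Camera with an estimated correlation and limma's fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were alternatives. The rule named Prf1 in every library, the 10 genes in each direction with the smallest unadjusted p among those whose groups did not overlap (because fewer than 5 passed the threshold), and up to 4 members of each list with the smallest unadjusted p. Predicted models, pseudogenes and receptor variable segments were left out of the rule. Some genes that the rule takes are not reported here. A few further genes were chosen after their values were seen and are said to be so.

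Other settings fixed in that way were the replicate number as a block, leaving out each library in turn, no filter on low values or a mean of at least 5, upper-quartile, median and quantile scaling, a pseudocount of 0.1 or 5, no intensity trend, robust moderation, an adjusted p threshold of 0.1 and an added fold threshold of 2. With a library left out, the lone library of a group was assumed to vary like the other group. Sample weights, and list tests without genes whose median transcript was under 700 bases, were added after the libraries had been compared. The procedure was tested on simulated data with the means and the fitted spread of the 9805 genes, in 5 runs with 200 changed genes each. The limma test recovered 0% of genes changed 2-fold, 52.8% of those changed 4-fold and 86.8% of those changed 8-fold. Figures were drawn with matplotlib 3.10.9.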

Results

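Perforin, encoded by Prf1, is the pore-forming protein of cytotoxic granules, and the labels frame the study as one of its role in diet-induced steatohepatitis. Gene expression was compared between hepatic CD8 T cells of MCD-fed wild type mice (2 libraries) and of MCD-fed mice labelled perforin knockout (2 libraries). Ubb, a ubiquitin gene, had the highest value in all 4 libraries. It stood at 10945 and 11225 in wild type replicates 1 and 2, and at 4559 and 10888 in the libraries labelled knockout.

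Prf1 RNA was present in all 4 libraries. Its FPKM was 125 and 113 in the wild type libraries and 95.4 and 98.7 in the libraries labelled perforin knockout, a ratio of means of 0.816. The log2 fold change was -0.29 (SE 0.24, 95% interval -0.83 to 0.25), with a limma adjusted p of 0.873 and an exact permutation p of 0.333, the smallest that 2 against 2 samples allow. The gene-level value thus did not show a loss of Prf1 RNA that would check the labels. Which part of the gene the allele removes is not given in the sources used here, and a value summed over the gene cannot show a short deletion. Every direction below is drawn from the labels alone.

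All 4 libraries carried the RNA of cytotoxic CD8 T cells. The coreceptor gene Cd8a had an FPKM of 286 ± 4.28 (SD, n = 2) in wild type and 280 ± 12.2 (SD, n = 2) in the libraries labelled knockout. Cd8b1 stood at 696 ± 58.4 and 697 ± 87.2. The serine protease gene Gzmb had 480 ± 30.5 and 519 ± 43.2, and the cytokine gene Ifng 464 ± 53.5 and 415 ± 161. These 4 genes were chosen after their values were seen, and none passed the test. H2-Ab1, an MHC class II gene of antigen-presenting cells, stood at 1291 and 592 in wild type and 412 and 651 in the libraries labelled knockout. Values below therefore need not come from T cells alone, and their cell source was not tested.

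**Figure D1:**
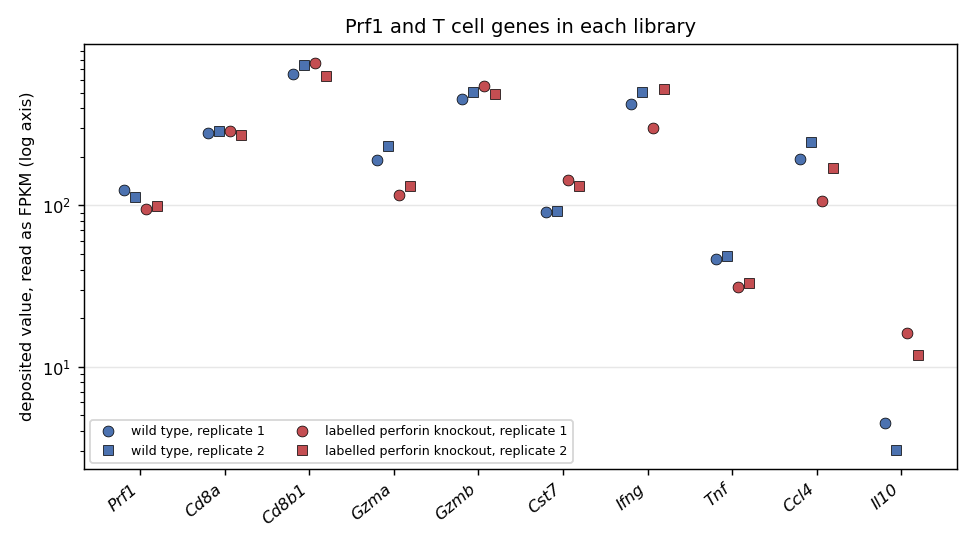
Deposited value, read as FPKM on a log axis, of Prf1 and 9 T cell genes in each library. Each point is 1 library, with circles for replicate 1 and squares for replicate 2. Prf1 lies between 95.4 and 125 in all 4 libraries.

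The question of the comparison was which genes differ between hepatic CD8 T cells with and without perforin. Genes with small p-values included the splicing factor gene Srsf2 and the integrin gene Itgae, lower in both libraries labelled knockout, and the cytokine gene Il10, higher in both, but none passed the threshold over all genes. Srsf2 had 337 ± 36.3 in wild type and 101 ± 5.94 in the libraries labelled knockout (log2 fold -1.73, SE 0.24, limma adjusted p = 0.450). Itgae, the integrin chain CD103 of tissue-resident T cells, had 12.1 and 35.3 in the wild type libraries and 3.51 and 4.80 in those labelled knockout (log2 fold -2.09, SE 0.47). Il10, an anti-inflammatory cytokine, had 3.76 ± 0.987 and 14.0 ± 3.12 (log2 fold 1.66, SE 0.34).

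Besides Srsf2 and Itgae, the 10 genes with the smallest p in the lower direction were the anion transporter gene Slc26a11 (log2 fold -2.53), the carbonic anhydrase gene Car2 (-1.66), Slc35d2 (-1.59), Rell1 (-1.36), Mettl23 (-1.36), the DNA end-joining gene Nhej1 (-1.28), Mettl2 (-1.25) and Adssl1 (-1.08). In the higher direction they were, besides Il10, the ribosomal protein genes Rps28 (3.75), Rpl38 (3.02) and Rps25 (2.20), the chemokine gene Cxcl3 (2.57), the transcription factor gene Gata4 (2.48), Rnf11 (2.21), the respiratory complex I gene Ndufa3 (1.60), the G protein signalling regulator Rgs16 (1.58) and Tm6sf1 (1.21). Values of Cxcl3 and Gata4 were low, with wild type means of 0.0965 and 0.204 against 5.61 and 6.20. Rps28, Rpl38 and Rps25 have processed copies in the genome, and Rps25, Rps28, Ndufa3, Mettl23, Rell1, Rgs16 and Tm6sf1 overlap another gene on the opposite strand, which unstranded reads cannot separate. These values are therefore uncertain, as are those of Csf1r, Eng, Gpr182, Hspa1a, Il12rb2, Cd7, Gins2, Oasl1, S1pr5, Satb1, Psmb9, Psme1 and Atp5o below for the same reason.

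**Figure D2:**
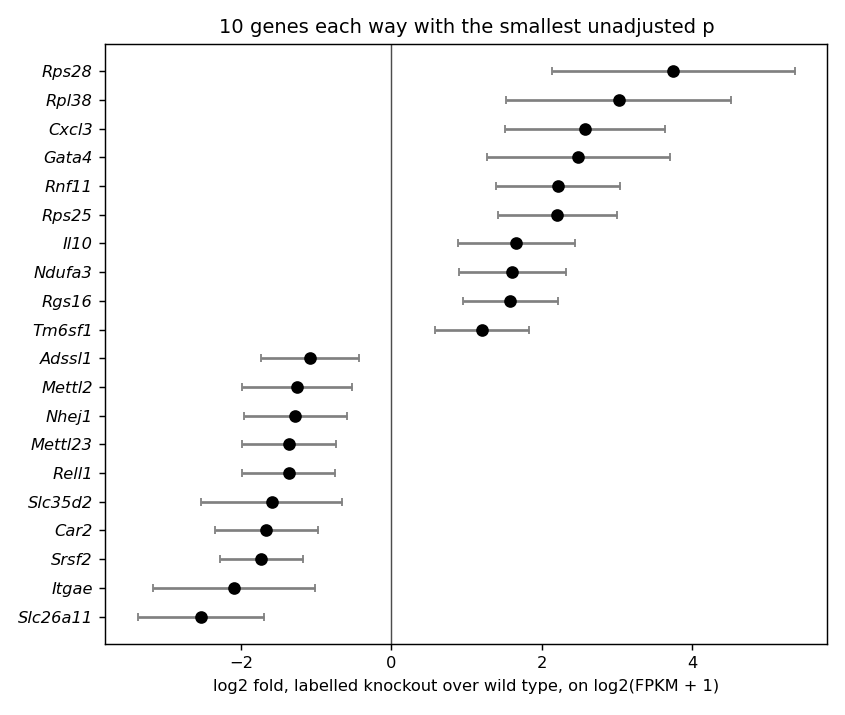
Log2 fold change, labelled knockout over wild type, on log2(FPKM + 1), of the 10 genes in each direction with the smallest unadjusted p among those whose groups did not overlap. Points are limma estimates and bars their unadjusted 95% intervals. Rps28 had the highest estimate of these genes (3.75) and Slc26a11 the lowest (-2.53), and none passed after adjustment.

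Of 9805 tested genes, 0 were higher and 0 lower in the libraries labelled knockout by limma at an adjusted p under 0.05, and the smallest adjusted p was 0.450. At an unadjusted p under 0.05 there were 470 genes, 203 higher and 267 lower, where chance gives 490. Limma without the trend, with robust moderation, with the replicate block or with sample weights also called 0. The 2 groups did not overlap for 3518 genes, or 35.9%, where chance gives 33.3%. Of these, 1367 were higher and 2151 lower in both libraries labelled knockout (13.9% and 21.9% of all tested genes), and this lean depended on scaling, with 1703 higher and 1816 lower after upper-quartile rescaling (17.4% and 18.5%), a count added after the values were seen. The share of tested genes with a positive log2 fold was 41.7%, and 49.0%, 46.4% and 47.3% with upper-quartile, median and quantile rescaling. The counts of list members higher or lower in both, given below, carry this lean. The median standard error was 0.34 on the log2 scale, and the simulated test found 0% of 2-fold changes, so changes of that size were not detectable. Single calls appeared with 1 library left out: Atp5k was higher without wild type replicate 2, and H2-Q6 lower without the library labelled knockout replicate 2. Of the 82 tested genes named besides Prf1, 50 had a log2 fold that changed sign or moved by over 1.5 times when 1 library was left out. Atp5k was named after its values were seen, and so was Ubb.

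The library labelled knockout replicate 1 stood apart from the other 3. Its Pearson correlation with each of them across genes, which are not independent replicates, was 0.914 to 0.924, while the other 3 correlated with each other at 0.961 to 0.969. The first principal component held 59.2% of the variance and placed it at 51.8, against -18.7 and -19.5 for the wild type libraries and -13.6 for the library labelled knockout replicate 2. It differed by more than 2-fold from all 3 others in the same direction for 549 genes, against 89, 78 and 41 genes for wild type replicates 1 and 2 and the library labelled knockout replicate 2.

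Of the 32 gene lists, 5 passed camera's threshold at the preset correlation. Ribosomal protein genes, immediate-early and dissociation stress genes, liver endothelial markers and macrophage and Kupffer cell markers rose as groups relative to other genes, and neutrophil markers fell. With an estimated correlation 0 of the 32 passed, with an adjusted p of 0.958 with an estimated correlation for each of these 5, and fry called 0 with a smallest adjusted p of 0.832. Over all genes 0 list members passed. Adjusted over the list alone, 5 did, namely Il10 (0.0159), Itgae (0.0356), Rps28 (0.0243), Rpl38 (0.0302) and Car2 (0.0026), with limma p-values. Without the library labelled knockout replicate 1, the median log2 fold changed sign in 13 of the 32 lists and moved by over 1.5 times in 13 others. The same count was not made for the other libraries, so a larger dependence on that library is not shown. The endothelial median, for example, moved from 0.77 to 0.03 without wild type replicate 2. Without wild type replicate 1, 8 passed, 4 of which did not pass with all libraries: tissue residency (adjusted p = 0.0214), proliferation (0.0178) and mitochondrial respiratory chain genes (0.0175), all downward, and gamma delta T cell and NKT cell markers (0.0359), upward. Without wild type replicate 2, 3 passed, among them proliferation genes upward (0.0043).

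Neutrophil markers were lower in both libraries labelled knockout for 8 of 14 tested genes and higher in both for 0. Their median log2 fold was -0.60 (camera adjusted p = 0.00218, and adjusted p = 0.958 with an estimated correlation). S100a8, a calcium-binding protein gene of granulocytes, had 137 and 130 in wild type and 32.7 and 87.3 in the libraries labelled knockout. Camp, an antimicrobial peptide gene, had 2.65 and 2.69 against 0 and 0.596. The colony-stimulating factor receptor gene Csf3r had 4.21 and 2.92 against 1.07 and 1.47. Ngp had 4.52 and 21.6 against 2.57 and 4.39, a log2 fold of -1.35 that was -0.33 without wild type replicate 2. The list passed without the library labelled knockout replicate 1 (adjusted p = 0.0187), and not without wild type replicate 2 (median -0.41, adjusted p = 0.0843). Among genes with a mean of at least 5, which left 6 members, the median was -0.60 and the adjusted p 0.156.

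In the immediate-early and dissociation stress list, 14 of 30 genes were higher in both libraries labelled knockout and 2 lower in both, with a median log2 fold of 0.12 (camera adjusted p = 0.0127, and adjusted p = 0.958 with an estimated correlation). The higher members included all 9 heat shock genes of the list, which encode inducible chaperones and their partners, with log2 folds of 0.49 to 1.70. Hspa1a had 287 and 1244 in wild type and 2013 and 1884 in the libraries labelled knockout. Hspa1b, Hsph1 and Hspe1 had log2 folds of 1.59, 1.18 and 1.34. Hspa1a and Hspa1b are near-identical and their split is uncertain. The other 21 members, mostly immediate-early genes, had a median of -0.14. The list did not pass without wild type replicate 1 (median 0.083, adjusted p = 0.668), without the library labelled knockout replicate 2 (0.22, adjusted p = 0.402) or without a filter on low values (0.12, adjusted p = 0.0504). Its median was 0.30 without wild type replicate 2 and 0.23 without the library labelled knockout replicate 1, and it passed in both.

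Ribosomal protein genes had a median log2 fold of 0.29 over 41 tested genes, with 12 higher in both libraries labelled knockout and 1 lower in both (camera adjusted p = 3.39e-05, and adjusted p = 0.958 with an estimated correlation). Rps28 had 0 and 2.16 in wild type against 46.1 and 11.1, Rpl38 9.60 and 24.1 against 280 and 61.4, and Rps15 a log2 fold of 0.67. The median FPKM over the list was 12.7 and 18.8 in the wild type libraries, 34.2 in the library labelled knockout replicate 1 and 14.8 in replicate 2. The uncertainty from processed copies, given above for single ribosomal protein genes, may reach other members. Whether it affects the list median was not tested. Without the library labelled knockout replicate 1 the list median was -0.06 and the call was lost (adjusted p = 0.910).

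Liver endothelial markers had a median log2 fold of 0.77 over 17 tested genes (camera adjusted p = 0.000461, and adjusted p = 0.958 with an estimated correlation), but 0 of the 17 were higher in both libraries labelled knockout. Replicate 1 exceeded replicate 2 for 17 of 17 genes in wild type and for 17 of 17 in the libraries labelled knockout. The list's median FPKM was 7.53 and 1.84 in wild type replicates 1 and 2, and 17.1 and 2.93 in the libraries labelled knockout. Eng had 17.3 and 5.49 against 84.9 and 9.52, and Lyve1, Gpr182 and Bmp2 had log2 folds of 1.61, 1.40 and 1.23. The call was lost without the library labelled knockout replicate 1, where the median was -0.09 (adjusted p = 0.910), and without wild type replicate 2 (0.03, adjusted p = 0.979).

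Macrophage and Kupffer cell markers had a median log2 fold of 0.80 over 13 tested genes, 4 higher and 1 lower in both libraries labelled knockout (camera adjusted p = 0.0102, and adjusted p = 0.958 with an estimated correlation). The receptor gene Csf1r had 17.1 ± 0.0353 and 31.3 ± 9.78 (SD, n = 2), and the haem-degrading enzyme gene Hmox1 30.5 ± 1.04 and 49.5 ± 7.05 (SD, n = 2). Spic, a Kupffer cell transcription factor, had a log2 fold of -0.94. The list's median FPKM was higher in replicate 1 of both groups, 8.51 and 3.78 in wild type replicates 1 and 2 and 11.7 and 4.01 in the libraries labelled knockout. Gene by gene, replicate 1 exceeded replicate 2 for 7 of 13 in wild type and 11 of 13 in the libraries labelled knockout, and for 6 in both, a looser pattern than in the endothelial list. The list did not pass without the library labelled knockout replicate 1 (0.06, adjusted p = 0.867) or without wild type replicate 2 (0.43, adjusted p = 0.495).

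**Figure D3:**
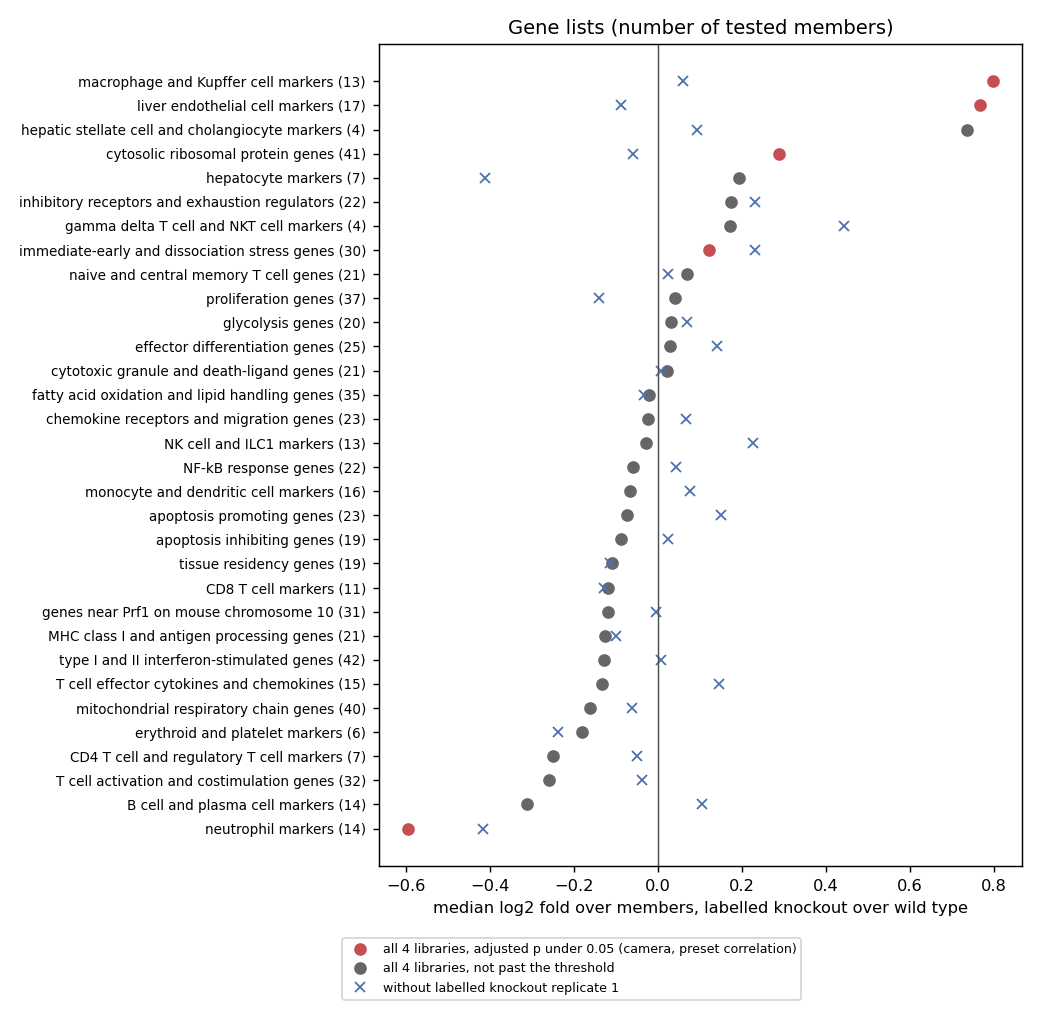
Median log2 fold change over the tested members of each of the 32 gene lists, labelled knockout over wild type. Circles show all 4 libraries, in red where camera at the preset correlation gave an adjusted p under 0.05, and crosses show the medians without the library labelled knockout replicate 1. The endothelial median moves from 0.77 to -0.09 and the neutrophil median stays below 0.

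The cytotoxic granule and death-ligand list did not pass, with 2 of 21 genes higher and 6 lower in both libraries labelled knockout (camera adjusted p = 0.952). Gzma, a granule protease gene, had 212 ± 31.1 and 124 ± 11.6 (SD, n = 2), while Cst7, which encodes a cysteine protease inhibitor of the granules, had 91.3 ± 0.433 and 137 ± 7.53 (SD, n = 2). The granule proteoglycan gene Srgn had a log2 fold of -0.62. Stxbp2 had 48.5 and 47.1 in wild type against 18.2 and 44.7, and its log2 fold of -0.72 was -0.092 without the library labelled knockout replicate 1. Among 15 effector cytokine and chemokine genes, 3 were higher and 4 lower in both (adjusted p = 0.593), and Ccl4 and Tnf had log2 folds of -0.71 and -0.55 beside the higher Il10.

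Inhibitory receptors went both ways, with 6 of 22 higher and 5 lower in both libraries labelled knockout (camera adjusted p = 0.443). Havcr2, which encodes TIM-3, had 10.9 and 4.15 in wild type against 16.2 and 16.6, and Lag3 a log2 fold of 0.70. Ctla4 and Cd160 had log2 folds of -0.76 and -0.62. Of 25 effector differentiation genes 6 were higher and 4 lower in both (adjusted p = 0.566), the higher ones including S1pr5 (0.85), Runx3 (0.67) and Il12rb2 (1.17). Tissue residency genes had a median of -0.11 with 2 of 19 higher and 6 lower in both (adjusted p = 0.566), among them Itgae and the purine receptor gene P2rx7 (-1.24). The list's call without wild type replicate 1 had no counterpart without replicate 2, where camera's direction was upward (adjusted p = 0.979). Naive and central memory genes had 5 of 21 higher and 4 lower in both (adjusted p = 0.593), with Dapl1 at -0.58 and Satb1 at 0.45.

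T cell activation and costimulation genes were lower in both libraries labelled knockout for 13 of 32 and higher for 2, or 10 and 2 after upper-quartile rescaling (median log2 fold -0.26 without it, camera adjusted p = 0.440), with Egr1 at -0.96 and the CD3 chain gene Cd3g at -0.62. Lat had 623 and 553 in wild type against 276 and 525. Without the library labelled knockout replicate 1 the list median was -0.038 and camera's direction upward (adjusted p = 0.997), with Egr1 at -0.46 and Lat at -0.16. Interferon-stimulated genes (42 tested, 6 higher and 9 lower, adjusted p = 0.978) included Oasl1 at 1.26 and Rtp4 at -0.71. MHC class I and antigen processing genes were lower in both for 6 of 21 and higher for 0, or 5 and 2 after upper-quartile rescaling (adjusted p = 0.589 without it), with the immunoproteasome genes Psmb9 at -0.59 and Psme1 at -0.56. NF-kB response genes gave 0.978, and chemokine receptor and migration genes 0.649, with the integrin gene Itgb1 at 0.70.

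Mitochondrial respiratory chain genes were lower in both libraries labelled knockout for 13 of 40 and higher for 0, or 10 and 3 after upper-quartile rescaling (median log2 fold -0.16 without it, camera adjusted p = 0.443), with Sdhb at -0.96 and Atp5o at -0.59. The list passed downward without wild type replicate 1 (adjusted p = 0.0175), while without wild type replicate 2 the direction was upward (0.942). Fatty acid oxidation and lipid handling genes had 8 of 35 higher and 7 lower in both (adjusted p = 0.589), with the lipase gene Lpl at 1.37 and Hadhb at -0.68. Glycolysis genes had an adjusted p of 0.643, with the kinase gene Pdk1 at -0.82. Proliferation genes gave 0.897, with Gins2 at -1.40, but passed downward without wild type replicate 1 (adjusted p = 0.0178) and upward without wild type replicate 2 (0.0043), so no direction is read from them. Genes that promote and inhibit apoptosis gave 0.952 each. Genes near Prf1 on mouse chromosome 10 could travel with a knockout allele if it had been backcrossed, which the sources used here do not say. They did not pass either (31 tested, 4 higher and 8 lower in both, camera adjusted p = 0.952). Camera tests a shared direction, so it cannot exclude changes of single neighbours in either direction.

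Of the remaining cell type lists, CD8 T cell markers had a median log2 fold of -0.12 (camera adjusted p = 0.589) and CD4 and regulatory T cell markers one of -0.25 (0.593). NK cell and ILC1 markers had -0.03 (0.952), with Cd7 at -1.09, B cell and plasma cell markers -0.31 (0.593), and monocyte and dendritic cell markers -0.07 (0.952). Hepatocyte markers (0.19, adjusted p = 0.897) had 7 tested genes, erythroid and platelet markers (-0.18, 0.593) 6, and stellate cell and cholangiocyte markers (0.74, 0.440) and gamma delta T cell and NKT cell markers (0.17, 0.566) 4 each. Without the library labelled knockout replicate 1 the median was -0.41 for hepatocyte markers, 0.10 for B cell and plasma cell markers, 0.23 for NK cell and ILC1 markers, 0.094 for stellate cell and cholangiocyte markers, 0.076 for monocyte and dendritic cell markers, -0.05 for CD4 and regulatory T cell markers and 0.44 for gamma delta T cell and NKT cell markers, while those of CD8 T cell (-0.13) and erythroid and platelet markers (-0.24) kept their sign and moved by less than 1.5 times. In 12 of the 32 lists, none of them past the threshold, the median, the mean and camera's direction did not share 1 sign.

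**Figure D4:**
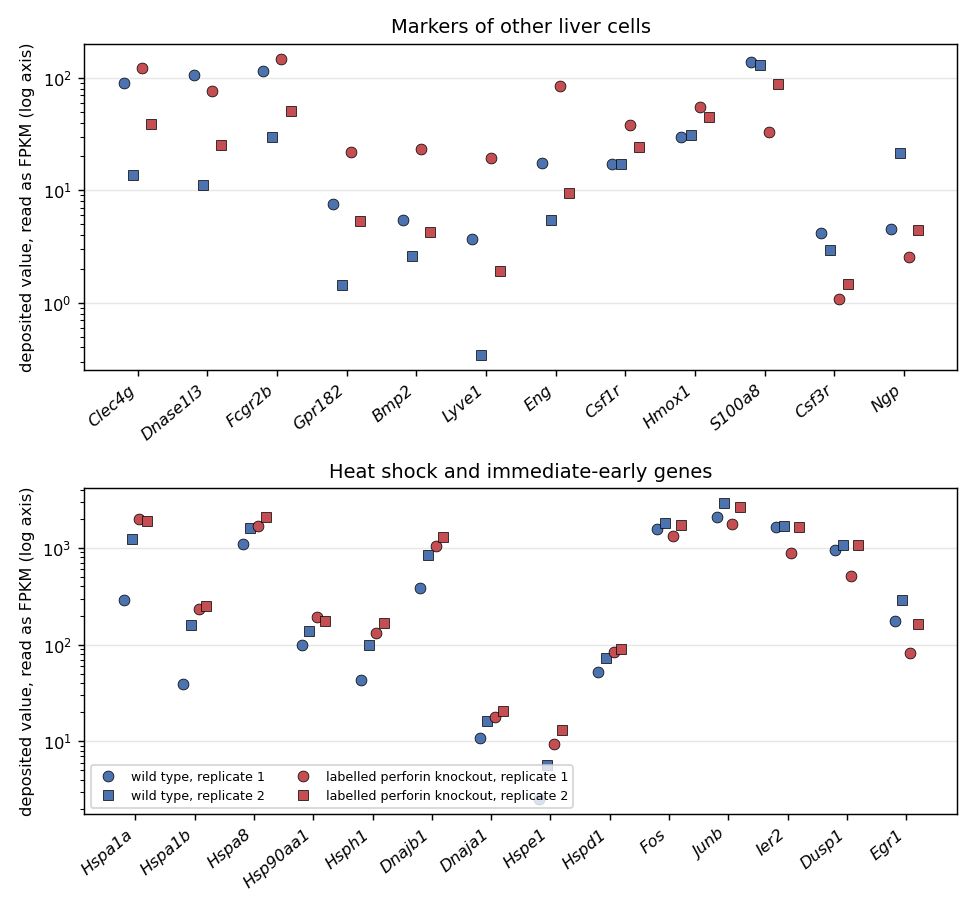
Deposited value, read as FPKM on log axes, in each library. The upper panel shows endothelial, macrophage and neutrophil markers, where the endothelial genes are higher in replicate 1 than in replicate 2 of both groups, and the lower panel shows heat shock and immediate-early genes. Hspa1a runs from 287 in wild type replicate 1 to 2013 in the library labelled knockout replicate 1.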

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

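Sample weights and the list tests without short transcripts were chosen after the libraries had been compared; all other settings were fixed earlier. The number of genes higher or lower in the libraries labelled knockout was 0 under every alternative that kept all 4 libraries, adjusted p under 0.1 included, and with a library left out it ranged from 0 to 1 in each direction. The log2 fold of Prf1 kept its sign and stayed short of the threshold throughout (-0.36 to -0.22 with a library left out). The number of lists past the threshold ranged from 2 to 8 with a library left out, and was 0 with an estimated correlation, 0 with fry and 4 to 6 under the other settings. Fewer samples lower the power of such a refit, and otherwise the cause was not tested. With the replicate block, 0 genes and 5 lists passed. Deviations of same-numbered samples correlated across all tested genes at 0.068 (2 pairs), and no label ties the numbers to a shared day or batch. Endothelial markers did go with the number. Their camera adjusted p at the preset correlation of 0.01 was 9.55e-11 with the block against 0.000461 without it. That of macrophage markers was 0.000299 against 0.0102. The endothelial markers moved together, with an estimated correlation between genes of 0.957, so they are not independent observations. With only 2 pairs, these p-values do not show a shared day, which stays open.

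Of 82 tested genes named besides Prf1, 8 changed sign with a library left out. Their log2 folds then ranged from -0.071 to 0.017 for Cd8a, -0.13 to 0.13 for Cd8b1, -0.051 to 2.98 for Eng, -7.15 to 0.24 for H2-Q6, -0.20 to 0.71 for H2-Q7, -0.62 to 0.19 for Ifng, -0.19 to 0.82 for Klrb1c and -0.93 to 0.33 for Tyrobp. The median of the liver endothelial list ranged from -0.087 to 1.65. Rescaling turned Cd8a from -0.027 to 0.053 (upper quartile), 0.025 (median) and 0.10 (quantile), and Cd8b1 from -0.00016 to 0.0803, 0.052 and 0.11 in the same order. The cause of these sign changes was not tested. Depth is unknown here, so whether weakly expressed genes were limited by it could not be assessed directly. The low end of the values did differ between libraries. Among genes with a median transcript of at least 3000 bases, the 5th percentile of values above 1e-06 was 0.102 and 0.0870 in wild type replicates 1 and 2. It was 0.0275 and 0.0905 in the libraries labelled knockout. Genes at 0 numbered 3258, 3206, 2872 and 3357 in the same order. The cause of this difference was not tested. Simulated 2-fold changes were recovered at 0%.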

Other observations

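The tests of explanations in this part were chosen after the values they concern had been seen, as were the bounds that decided them.

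RNA of genes typical of antigen-presenting and myeloid cells was present in all 4 sorted libraries, and its cell source was not tested. Lyz2, the lysozyme gene of myeloid cells, had an FPKM of 2387 and 2510 in wild type and 1508 and 2391 in the libraries labelled knockout, while Csf1r had 17.1 to 38.2. The MHC class II gene H2-Ab1 had 1291 and 592 against 412 and 651, and its partner Cd74 1449 and 645 against 503 and 807. Lyz2, H2-Q7 and, below, Ncr1 and Tyrobp were chosen after their values were seen. The library labelled knockout replicate 1 differed from the other 3 in closely related genes, of which these were picked after their values were seen. Hbb-b1 had 16.6, 14.7 and 13.7 in the other libraries and 0.0277 in that one, where Hbb-bs had 21.3 and elsewhere at most 0.00431. H2-Q6 had 104, 195 and 169 in the other libraries and 0.00843 in that one, and its relative H2-Q7 had 108 there and at most 67.6 elsewhere, a smaller difference than that of H2-Q6.

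Prf1 RNA was present in both libraries labelled knockout. NK cells also express Prf1, and a sort for CD8 would leave them out. The highest of the NK cell genes Ncr1, Klrb1c and Tyrobp in those libraries was 5.28 (Tyrobp), against a Prf1 value of at least 95.4. RNA of these NK cell genes was thus low beside that of Prf1, but this does not decide the source. NK cells of the same animals would carry the same allele where all cells have it. A wrong label on 1 library, or an exchange of labels among the 4, would show only with an allele that removes the RNA. At least 1 library would then lack it. The lowest Prf1 value was 0.765 of the highest, which argues against such an allele in any of the 4 libraries. Right labels with such an allele are argued against alike, so the ratio does not decide between right and exchanged labels. With an allele that leaves the RNA, an exchange would not change these values, so it stays open. That both libraries labelled knockout are wild type stays open and cannot be told apart from an allele that leaves most of the transcript, since the ratio of the group means, 0.816, is what either may give and the values are summed over the gene.

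The library labelled knockout replicate 1 stood apart from the other 3. Endothelial RNA is argued against as the whole cause, since wild type replicate 1, which also had the endothelial markers, lay 0.84 from wild type replicate 2 on the first component, where the libraries labelled knockout lay 65.4 apart. Counting noise in weakly expressed genes is argued against as the whole cause too. Among 1419 genes with a mean of at least 50 the smallest median difference of that library to another was 0.377 (log2), against at most 0.180 among the other 3. Its part in the separation over all tested genes was not tested. Where the labels are right, a genotype shared by both libraries labelled knockout is not the whole cause by itself, since replicate 2 lay at -13.6 on that component, beside the wild type libraries at -18.7 and -19.5 and far from replicate 1 at 51.8, while a part of the genotype in it stays open. A difference in library preparation or in the assignment of reads stays open too. The values of Hbb-b1, Hbb-bs and H2-Q6 in that library, given above and picked after being seen, bear on the assignment of reads. No test of either was made, and no label names such a difference.

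All 9 heat shock genes of the stress list were higher in both libraries labelled knockout. A dissociation response that raises the whole list alike is argued against by the other 21 members. They had a median log2 fold of -0.137, with 10 above 0, where the median over all tested genes was -0.080. Some of the 21 rose as well, since the list had 14 genes higher in both, the 9 heat shock genes among them, and 2 lower in both. The upper quartile of the 21 was 0.166, below the lowest heat shock gene at 0.493. A dissociation response carried mainly by the heat shock genes, which were set apart after their values were seen, is not covered by this and stays open. Handling that differed between single libraries is a candidate explanation. The 2 wild type libraries differed in the heat shock genes by a median of 0.925, more than the 0.470 between the labelled knockout mean and wild type replicate 2. That is the nearer wild type library, and the median log2 fold between the groups was 1.03. The libraries labelled knockout had 2013 and 1884 for Hspa1a and 131 and 168 for Hsph1, and their spread over all 9 genes was not computed. The genotype stays open as well, untested.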
